A study of Mus musculus with 12 samples.

How the data were processed

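Polysome-bound RNA of mouse oocytes (C57BL/6, postnatal day 21) was sequenced in WT and Cnot6l-/- mice at 3 stages, GV, MI and MII, with 2 libraries for each of 6 groups, 12 in all. GV oocytes came 48 h after PMSG, and MI and MII oocytes after 8 h and 16 h of culture. Libraries were made with Tn5 transposase from 500 pg of pre-amplified cDNA. The labels give no litter, day or sequencing run, and do not say whether replicates are separate pools, so replicate numbers were not treated as pairs.

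The authors deposited FPKM values (fragments per kilobase of transcript, scaled by library size) for 23235 genes in 1 table of all libraries and in 1 table per library; the 2 versions hold the same values to 2 decimals. Per the submitters' processing notes, CASAVA 1.8, TopHat2 2.0.11, Bowtie2 2.1.0, Cufflinks 2.2.1 and mouse build 9 were used, with no role or order stated. The annotation, read filters, any spike-in and read counts are not given in the sources used here. The deposited FPKM were used as they are, since their totals differ between libraries and the factor behind each total is unknown. Depth in reads is unknown too. Low FPKM fall on steps of whole reads, but the steps of WT MI and WT MII leave room for a factor of 2, so they were not used. The precision of single genes is therefore judged from replicates alone: across genes Pearson's r of log2 values within a group was 0.865 to 0.949. Symbols were matched to an annotation of the same build (GENCODE mouse release 1) for transcript lengths; 94.1% were found, and 97.7% of tested genes had a length.

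Groups, comparisons, tests, gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. Values were analysed as log2(FPKM + 1) for the 11667 genes with a mean FPKM of at least 1 over the 12 libraries. limma 3.58.1 in R 4.3.3 fitted 6 group means with residual df 6 and empirical Bayes moderation with an abundance trend (prior df 4.27). Contrasts were KO minus WT at each stage, MI minus GV and MII minus MI in each genotype, and the difference of these stage changes between genotypes (interaction). Genes with a Benjamini-Hochberg adjusted p below 0.05, 2-sided, count as called, and a positive value means higher in the group named before vs. FPKM values per group are mean ± SD of 2 libraries; genes at 0 in a whole group get no fold change. In a simulation of KO vs WT at MI, limma recovered 15 of 100 genes changed by 1 (log2) and 37 of 99 by 2. It also called 5 of 11467 unchanged genes (8.62% of 58 calls) and 1 changed gene not counted, its decrease cut at 0. The design was the same but most genes were unchanged, unlike in real MI data, where rates may differ.

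Named genes are, per KO vs WT comparison and per WT stage comparison, drawn from the 8 largest increases and the 8 largest decreases among called genes whose libraries do not overlap and whose mean FPKM is at least 5 in the higher group, from up to 4 called members with the largest change in each gene list, and from the fixed genes Cnot6l, Cnot6, Cnot7, Btg4, Zfp36l2, Ccnb1, Mos, Gdf9, Bmp15 and Zp3. Symbols of predicted genes and small RNAs, and those with 2 loci, were skipped. The text gives a part of them. The 20 lists cover CCR4-NOT and deadenylases; decapping, exosome and terminal uridylation; maternal RNA-binding regulators; zona pellucida and subcortical maternal complex; oocyte-specific factors; meiotic cell cycle control; spindle, kinetochore and centrosome genes. They also cover maternal transcripts with a cytoplasmic polyadenylation element that are translated on maturation, ribosomal proteins, translation factors, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, the proteasome, DNA replication and licensing, DNA methylation and chromatin modifiers, and the transcription machinery. The last lists are early embryonic genes, cumulus and granulosa markers, theca, stroma, endothelium and blood markers, and heat shock, unfolded protein and p53 response. Some genes are in more than 1 list, and Cnot6l was left out of every list test. The 17 lists with at least 5 tested genes were tested with limma camera at a preset correlation of 0.01 and with an estimated one, adjusted over lists within a comparison.

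The stage position of a library is its projection on the line from the WT GV mean to the WT MII mean. Sets of genes called in WT stage comparisons were compared with other genes by camera in KO vs WT contrasts at the stage that was not part of the WT comparison. The calls behind the sets use a spread pooled over all 12 libraries, so the sets were also chosen and compared in separate fits of the groups involved. Shared calls between stages were tested with Fisher's exact test, 2-sided, against all tested genes. The alternatives were a pseudocount of 0.1, no filter, FPKM rescaled to the same total per library (TPM), median scaling (over genes with a mean FPKM of at least 10), quantile normalization, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Removal of each library's trend with transcript length and with abundance was chosen after seeing the data. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. No data were left out.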

Results

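Polysome-bound RNA of wild-type (WT) and Cnot6l-/- (KO) mouse oocytes was compared at the germinal vesicle (GV), MI and MII stages, with 2 libraries in each of 6 groups. Cnot6l, which encodes a catalytic deadenylase subunit of the CCR4-NOT complex, lies on chromosome 5 (96505816 to 96591009, mouse build 9). Its FPKM in the WT libraries was 38.7 and 16.1 at GV, 68.5 and 47.9 at MI and 65.2 and 49.4 at MII, against 6.28 and 21.6, 23.5 and 16.5 and 16.4 and 16.0 in KO. The KO GV libraries overlapped those of WT GV, so the genotype was not readable from Cnot6l at that stage. Every KO library kept some signal over the gene. The labels do not say which part of the gene was deleted. The log2 difference KO minus WT was -1.02 at GV (limma adjusted p = 0.626), -1.49 at MI (adjusted p = 0.0726) and -1.75 at MII (adjusted p = 0.0425). The MII call was lost without WT MI replicate 1 (0.0529) or 2 (0.0524), WT MII replicate 1 (0.141) or 2 (0.0689), KO MI replicate 1 (0.0624) or 2 (0.0616), or KO MII replicate 1 (0.134) or 2 (0.141). Over all alternatives its adjusted p was 0.0105 to 0.141. At MI the gene was called without KO GV replicate 1 (0.0412) or 2 (0.0434).

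The deposited FPKM do not sum to the same total. Totals were 1252142 and 1280736 in WT GV, 1040466 and 1063273 in WT MI, 889989 and 884142 in WT MII, 1067558 and 1071813 in KO GV, 1635234 and 1663871 in KO MI, and 1211628 and 1213953 in KO MII. Genes above 0 numbered 9064 to 9116 in WT MII and 13277 to 13319 in KO MI. Most genes therefore moved at once between some groups. The median log2 difference KO minus WT was -0.06 at GV, 1.03 at MI and 0.81 at MII. Between stages it was -0.87 for WT MI vs GV, -0.27 for WT MII vs MI, 0.26 for KO MI vs GV and -0.59 for KO MII vs MI. No external standard is given, so the plot of KO minus WT differences across all genes shows a shift whose scale cannot be read from these values. Changes of genes are given as deposited and, marked relative, after subtracting the median of all genes tested. Splits after dividing each library by a median ratio (median scaling) stand beside those as deposited. Pearson's r between the replicates of a group, across genes and on the log2 scale, was 0.865 (WT MII) to 0.949 (KO MI). The median absolute difference between replicates was 0.526 in WT MII and 0.309 in KO MI, while the fit takes 1 spread per gene for all groups. Genes at 0 in 1 library and above 20 FPKM in the other numbered 20 in WT GV, 39 in WT MI and 105 in WT MII. In KO GV, KO MI and KO MII they numbered 34, 9 and 13. A listed 0 therefore does not show that a transcript was absent, least of all in WT MII. Genes are not independent replicates. The p-values measure spread between libraries, which may be technical, since the labels do not say how the replicates were drawn.

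**Figure D1:**
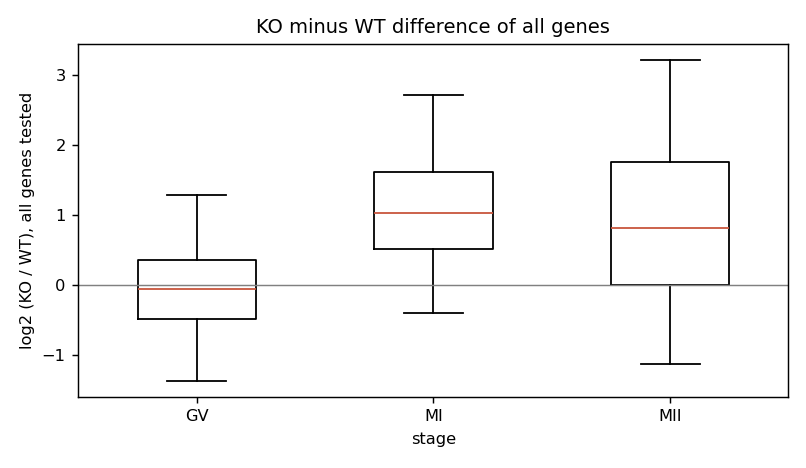
KO minus WT difference (log2 of FPKM + 1, vertical axis) of the 11667 genes tested at GV, MI and MII; boxes span the quartiles with a line at the median, and whiskers run from percentile 5 to percentile 95. The medians are -0.06, 1.03 and 0.81.

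On a line from the WT GV mean (position 0) to the WT MII mean (position 1), WT MI libraries lay at 0.520 ± 0.0017 (mean ± SD of 2 libraries), KO GV at 0.0787 ± 0.0056, KO MI at 0.103 ± 0.0038 and KO MII at 0.376 ± 0.0082. As deposited, KO MI libraries thus lay nearer to the GV groups than to WT MI on the wild-type stage axis, and KO MII libraries lay short of WT MI by more than the spread between replicates. With median scaling the groups kept this order, but KO MI lay farther from both GV groups, about midway between WT GV and WT MI, and KO MII lay nearer to WT MI. The positions were then 0.40 and 0.405 for the WT MI libraries, 0.201 and 0.20 for KO MI, 0.341 and 0.351 for KO MII, and 0.0655 and 0.0555 for KO GV. No test was run on these positions.

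**Figure D2:**
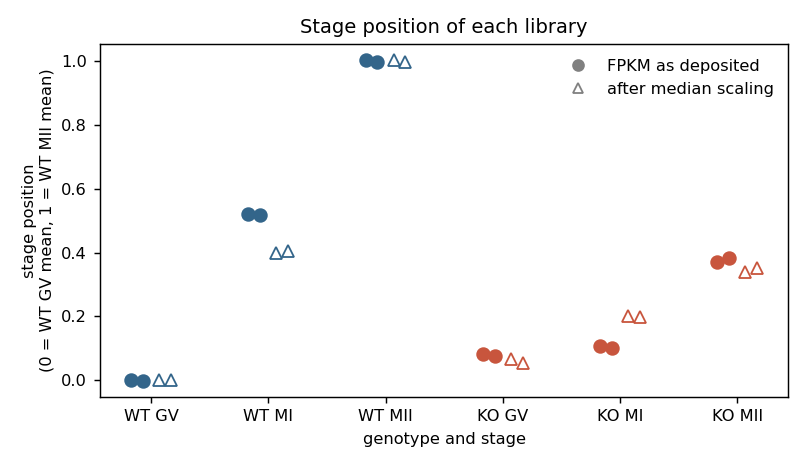
Position of each of the 12 libraries (vertical axis, no unit) on the line from the WT GV mean (0) to the WT MII mean (1), by group, as deposited (filled circles) and with median scaling (open triangles). KO MI libraries lie at 0.101 and 0.106 and KO MII libraries at 0.370 and 0.382 as deposited, all below the WT MI libraries at 0.519 and 0.522.

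In WT oocytes going from GV to MI, more polysome-bound transcripts fell than rose as deposited, and the risers included many maternal transcripts. limma called 357 genes higher and 2535 lower, with a median change of -0.87. With median scaling the split was 919 higher and 745 lower, and 12 genes called lower were then called higher. Without WT GV replicate 2 or 1 the lower calls numbered 1176 or 1227, and the higher calls numbered 216 without WT GV replicate 1. Of the 20 transcripts listed as carrying a cytoplasmic polyadenylation element and translated on maturation, 11 rose, 2 fell and 7 were not called (12 and 2 adjusted over the list alone). With median scaling 14 and 0 were called in these directions. The camera test gave adjusted p = 2.8e-11, and 0.0140 with an estimated correlation. They included the cell cycle kinase Mos (1.40, adjusted p = 1.8e-06, 2.27 relative to the median), cyclin B1 (Ccnb1, 1.20, adjusted p = 1.2e-05, 2.06 relative) and the origin protein Orc6 (1.65, adjusted p = 1.3e-04, 2.52 relative). The deadenylation adaptor Btg4 rose by 1.03 (adjusted p = 2.9e-07), as did the deadenylases Cnot7 (0.91, adjusted p = 0.00161) and Cnot8 (1.16, adjusted p = 7.3e-04).

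Oocyte-specific factors moved the same way from GV to MI in WT: 17 of 30 rose, 5 fell and 8 were not called (17 and 6 adjusted over the list alone), among them the oocyte genes Rfpl4 (2.39 and 3.25 relative, adjusted p = 6.8e-07), Obox5 (2.06 and 2.92 relative, adjusted p = 8.9e-08), Oosp1 (2.02 and 2.89 relative, adjusted p = 3.1e-08) and the growth factor Gdf9 (0.89 and 1.76 relative, adjusted p = 4.2e-06). With median scaling 20 and 1 were called in these directions. By camera it had adjusted p = 1.3e-10, and 0.0221 with an estimated correlation. With the abundance trend of each library removed, a setting chosen after seeing the data, the list no longer passed camera (adjusted p = 0.690). There Btg4 and Gdf9 had the opposite sign (-0.31 and -0.55; adjusted p over the alternatives 1.4e-09 to 0.0152 and 2.2e-08 to 0.0170), and Ccnb1 was no longer called (2.4e-07 to 0.101 over the alternatives). The zona glycoprotein Zp3 fell by 0.35 as deposited (adjusted p = 1.4e-04) but was 0.44 higher with median scaling, and was not called when every library was rescaled to the same total (adjusted p over the alternatives 6.6e-10 to 0.10). The lists for meiotic cell cycle control (9 rose, 7 fell, 21 not called, of 37; 9 and 0 with median scaling) and for spindle, kinetochore and centrosome (7 rose, 8 fell, 31 not called, of 46; 16 and 3 with median scaling) lay above other genes by camera (adjusted p = 0.0036 and 0.00267; 0.0267 and 0.0231 with an estimated correlation). The median of each list as deposited was negative (-0.29 and -0.01), so both rose only relative to the median of all genes. Neither passed camera with the abundance trend removed (adjusted p = 0.378 and 0.0699). Adjusted over the list alone, 9 and 7 cell cycle members rose and fell, and 7 and 8 spindle members.

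Ribosomal protein and proteasome transcripts fell from GV to MI in WT beyond the shift of all genes. Ribosomal protein transcripts fell in 63 of 80 cases, with 0 higher and 17 not called (67 lower and 1 higher adjusted over the list alone), for example Rpl23 (-2.79 and -1.92 relative, adjusted p = 3.2e-04) and Rpl28 (-2.64 and -1.77 relative, adjusted p = 1.9e-06). With median scaling 34 lower and 6 higher were called. In the camera test the list had adjusted p = 1.3e-11, and 0.00125 with an estimated correlation. At an unadjusted p under 0.05 limma had 514 genes higher and 3898 lower. Proteasome transcripts fell in 26 of 35 cases and rose in 1, with 8 not called (26 and 1 adjusted over the list alone), for example Psmc2 (-3.29 and -2.42 relative, adjusted p = 1.7e-04) and Psmb4 (-2.38 and -1.52 relative, adjusted p = 2.1e-05). With median scaling 13 and 5 were called in these directions. Against other genes camera gave adjusted p = 8.5e-04, and 0.0221 with an estimated correlation. Nuclear-encoded oxidative phosphorylation transcripts fell in 48 of 85 cases and rose in 5, with 32 not called (54 and 7 adjusted over the list alone), for example Sdhb (-2.59 and -1.72 relative, adjusted p = 3.9e-05) and Ndufv2 (-2.46 and -1.60 relative, adjusted p = 0.00125). With median scaling 20 and 13 were called in these directions. The list had a camera adjusted p = 0.0121, but adjusted p = 0.0947 with an estimated correlation, and 0.0506 without WT GV replicate 2. That list also did not pass with median scaling (0.454) or TPM, FPKM rescaled to the same total per library (0.0511), so a decrease of it beyond the shift depended on the setting. Translation factors fell in 22 of 60 cases and rose in 2, with 36 not called (24 and 4 adjusted over the list alone; 12 and 8 with median scaling). They did not pass camera as deposited (adjusted p = 0.0937), but did without the filter (0.0198) or with the abundance trend removed (0.00532). Other large decreases were the initiation factors Eif3m (-3.77 and -2.90 relative, adjusted p = 1.7e-05) and Eif2b2 (-3.15 and -2.28 relative, adjusted p = 2.9e-04), the maternal RNA-binding genes Zar1l (-2.56 and -1.70 relative, adjusted p = 5.2e-04) and Igf2bp2 (-2.01 and -1.15 relative, adjusted p = 4.2e-04), and the kinase gene Stk36. Stk36 was at 79.7 and 80.9 FPKM in WT GV and 3.26 and 0 in WT MI (-5.30, adjusted p = 2.3e-04). Some changes involved genes that cumulus cells also express: Ptx3 and Tnfaip6, of the cumulus matrix, were listed at 0 in both WT GV libraries. In WT MI Ptx3 was at 32.1 and 40.2 FPKM and Tnfaip6 at 7.88 and 5.79. The inhibin subunit gene Inha dropped from 219.9 ± 26.8 to 30.2 ± 10.5 FPKM (mean ± SD, log2 change -2.86, adjusted p = 0.00200).

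From MI to MII in WT, transcripts of ribosomal proteins, oxidative phosphorylation and the proteasome fell beyond the shift of all genes. limma called 663 genes higher and 1911 lower (1331 and 1561 with median scaling), with a median change of -0.27. A fit of WT MI and WT MII alone called 0 genes by limma (857 higher and 1780 lower at an unadjusted p under 0.05, lowest adjusted p 0.0582), so every call here rests on the spread pooled over all 12 libraries. Replicates differed most in WT MII (median absolute log2 difference 0.526), so a pooled spread can make adjusted p-values of its comparisons too small. Ooep, Padi6 and Tle6, which encode subcortical maternal complex proteins, fell by 3.13 (SE 0.0885, adjusted p = 6.6e-09), 2.12 (SE 0.0448, adjusted p = 8.2e-10) and 2.1 (SE 0.0517, adjusted p = 2.5e-09), and Zp3 fell by 1.69 (adjusted p = 8.2e-10). In their list 7 of 10 fell, 1 rose and 2 were not called (7 and 1 adjusted over the list alone). With median scaling 6 and 2 were called in these directions. Camera gave this list adjusted p = 0.0101, but adjusted p = 0.152 with an estimated correlation. With median scaling it did not pass either (0.0795). Of the oocyte-specific factors 18 of 30 fell, 2 rose and 10 were not called (19 and 2 adjusted over the list alone), including the histone chaperone Npm2 (-3.00 and -2.73 relative, adjusted p = 2.0e-07), Nobox (-1.86 and -1.60 relative, adjusted p = 3.4e-06), Bmp15 (-1.31 and -1.04 relative, adjusted p = 6.4e-07) and Gdf9 (-0.91 and -0.64 relative, adjusted p = 2.2e-06). With median scaling 13 and 7 were called in these directions. The camera test gave adjusted p = 0.0119, but adjusted p = 0.229 with an estimated correlation. They did not pass with TPM (0.0755), median scaling (0.151) or quantile normalization (0.0678). Ribosomal protein transcripts fell in 53 of 80 cases and rose in 3, with 24 not called (59 and 3 adjusted over the list alone), for example Rps9 (-3.22 and -2.95 relative, adjusted p = 2.9e-06) and Rps27a (-3.07 and -2.81 relative, adjusted p = 1.9e-06). With median scaling 41 and 7 were called in these directions. By camera it had adjusted p = 2.2e-08, and 0.00354 with an estimated correlation.

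Also from MI to MII in WT, nuclear-encoded oxidative phosphorylation transcripts fell in 52 of 85 cases and rose in 1, with 32 not called (54 and 2 adjusted over the list alone), for example Ndufb7 (-3.97 and -3.70 relative, adjusted p = 2.1e-04). With median scaling 38 and 6 were called in these directions. In the camera test the list had adjusted p = 2.2e-08, and 0.0110 with an estimated correlation. Proteasome transcripts fell in 20 of 35 and rose in 2, with 13 not called (23 and 2 adjusted over the list alone), for example Psmc1 (-4.76 and -4.50 relative, adjusted p = 6.3e-07) and Psmb1 (-3.31 and -3.04 relative, adjusted p = 1.2e-06). With median scaling 19 and 4 were called in these directions. Against other genes camera gave adjusted p = 3.7e-05, and 0.0112 with an estimated correlation. Translation factors fell in 20 of 60 and rose in 4, with 36 not called (24 and 5 adjusted over the list alone), among them Eif2s3x (-3.84 and -3.57 relative, adjusted p = 9.2e-05) and Eif4h (-3.66 and -3.40 relative, adjusted p = 3.4e-06). The list had a camera adjusted p = 0.0119, but adjusted p = 0.0516 with an estimated correlation. Translation factors did not pass with TPM (0.0552) or median scaling (0.105; 18 fell and 5 rose). Single cell cycle transcripts fell steeply: the kinase Cdk1 (-3.77 and -3.51 relative, adjusted p = 1.0e-05), the checkpoint kinase Bub1 (-3.44 and -3.17 relative, adjusted p = 6.2e-04), the spindle gene Tacc3 (-4.30 and -4.04 relative, adjusted p = 4.3e-09) and the helicase subunit Mcm5 (-4.8 and -4.54 relative, adjusted p = 2.4e-06). The poly(A)-binding regulators Paip2 (-2.79 and -2.52 relative, adjusted p = 3.2e-06) and Pabpc1l (-2.24 and -1.98 relative, adjusted p = 1.1e-05) fell as well. So did the chaperones Hspa8 (-2.28 and -2.01 relative, adjusted p = 6.7e-08) and Dnaja1 (-2.68 and -2.41 relative, adjusted p = 1.8e-06). Mrpl55 was listed at 46.0 and 45.0 FPKM in the WT MI libraries and Dscc1 at 37.7 and 43.0. Both were at 0 in both WT MII libraries. Of the 20 maturation transcripts with a polyadenylation element, 8 rose, 3 fell and 9 were not called (11 and 4 adjusted over the list alone). With median scaling 14 and 2 were called in these directions. Camera gave this list adjusted p = 0.00254, but adjusted p = 0.126 with an estimated correlation. The decapping genes Dcp1a (2.16 and 2.42 relative, adjusted p = 1.7e-05) and Edc4 (1.03 and 1.29 relative, adjusted p = 0.00517) rose, as did Wee2 (1.11 and 1.37 relative, adjusted p = 0.00220), Bub1b (0.99 and 1.26 relative, adjusted p = 3.0e-05), Plat (0.84 and 1.11 relative, adjusted p = 2.3e-05) and Ccnb1 (0.41 and 0.68 relative, adjusted p = 0.00755). As lists, decapping, exosome and uridylation genes gave 5 higher, 2 lower and 15 not called of 22 (6 and 2 within the list alone; 8 and 0 with median scaling) and meiotic cell cycle control 3 higher, 11 lower and 23 not called of 37 (5 and 13 within the list alone; 12 and 7 with median scaling). Neither passed camera as deposited (adjusted p = 0.0564 and 0.719; 0.143 and 0.728 with an estimated correlation). The decapping list passed in a fit of WT MI and WT MII alone (0.0265), without WT MII replicate 2 (0.0327) and without either KO GV library (0.0430). Mos was not called (-0.06, adjusted p = 0.665) and was called higher with median scaling (0.33; adjusted p over the alternatives 0.0139 to 1). Btg4 fell by 0.40 (adjusted p = 1.6e-04) but changed by -0.01 with median scaling (adjusted p over the alternatives 1.6e-04 to 0.936).

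At GV, before meiotic resumption, few transcripts were called between KO and WT oocytes, and most of those were lower in KO. Of the 50 genes most abundant in WT GV, a group chosen after seeing the data, 30 were called lower and 2 higher. Ranking by the WT GV libraries that are also compared favours lower values in KO. limma called 19 genes higher and 163 lower in KO (21 and 100 with median scaling). With TPM these were 48 and 76, and with quantile normalization 50 and 88. At an unadjusted p under 0.05 there were 378 and 844 as deposited. With 2 libraries per group, few calls do not show that few transcripts differed. Leaving out single libraries moved both counts of calls, as given below. In a fit of the 4 GV libraries alone limma called 0 genes (480 higher and 1052 lower at an unadjusted p under 0.05; lowest adjusted p 0.0844). Transcripts that fell included the securin gene Pttg1 (-1.18, adjusted p = 5.3e-08), the maternal RNA-binding gene Zar1 (-0.83, adjusted p = 3.1e-05), the subcortical complex gene Tle6 (-0.83, adjusted p = 1.8e-05), the zona gene Zp3 (-0.67, adjusted p = 8.2e-06), the ubiquitin hydrolase gene Uchl1 (-1.08, adjusted p = 1.8e-05), the zona-cleaving protease gene Astl (-0.69, adjusted p = 7.6e-04) and Oas1d (-0.77, adjusted p = 9.0e-04). Zar1 and Zp3 were not called after quantile normalization (adjusted p over the alternatives 1.5e-05 to 0.137 and 5.3e-06 to 0.615). Oocyte-specific factors fell in 9 of 30 cases and rose in 1, with 20 not called (13 and 3 adjusted over the list alone). The camera test gave adjusted p = 0.00227, but adjusted p = 0.182 with an estimated correlation. Zona and subcortical complex genes fell in 4 of 10, with 0 higher and 6 not called (5 lower adjusted over the list alone). By camera it had adjusted p = 0.00482, but adjusted p = 0.169 with an estimated correlation, and 0.0506 without KO GV replicate 1. Neither of these 2 lists passed with TPM (0.0866 and 0.130), quantile normalization (0.664 and 0.664) or the abundance trend removed (0.772 and 0.772).

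Also at GV, proteasome genes fell in 5 of 35 cases, with 0 higher and 30 not called (8 lower adjusted over the list alone), for example Psmb2 (-1.02, adjusted p = 0.00160). With median scaling 1 lower and 0 higher were called. In the camera test the list had adjusted p = 6.4e-06, and 0.0182 with an estimated correlation. Translation factors fell in 3 of 60, with 0 higher and 57 not called (5 lower adjusted over the list alone). Against other genes camera gave adjusted p = 0.00266, and 0.0429 with an estimated correlation. Oxidative phosphorylation transcripts fell in 5 of 85, with 0 higher and 80 not called (8 lower adjusted over the list alone). The list had a camera adjusted p = 8.4e-04, but adjusted p = 0.0605 with an estimated correlation. Neither translation factors nor oxidative phosphorylation passed with TPM (0.0609 and 0.0609), quantile normalization (0.0699 and 0.301) or the abundance trend removed (0.0923 and 0.337). The ribosomal protein list did not pass the camera threshold (6 lower, 0 higher and 74 not called of 80, and 6 lower adjusted over the list alone; camera adjusted p = 0.213), although Rpl10 (-1.32, adjusted p = 1.7e-04) and Rpl5 (-1.47, adjusted p = 0.00209) fell. The general transcription factor gene Gtf2b (-1.03, adjusted p = 0.00133) fell too. Spindle genes fell in 2 of 46 (44 not called, 4 lower adjusted over the list alone) and DNA replication genes in 1 of 35 (34 not called, 1 lower adjusted over the list alone), each with camera adjusted p = 0.0317, adjusted p = 0.104 and 0.19 with an estimated correlation. The spindle call was lost without WT GV replicate 1 (0.0576) or 2 (0.105) or KO GV replicate 1 (0.106) or 2 (0.0853), and the replication call without WT GV replicate 1 (0.201) or KO GV replicate 1 (0.247). Both calls were also lost with a pseudocount of 0.1, TPM, median scaling, quantile normalization or the abundance trend removed. The secreted protein gene Dcpp1 was listed at 23.2 and 19.8 FPKM in WT GV and 0 in both KO GV libraries, and its paralog Dcpp2 at 17.4 and 17.9 and 0. Reads shared between the pair leave their separate values uncertain. The Dcpp2 call was lost without WT GV replicate 2 (adjusted p = 0.0517). The transcription factor gene Jun was listed at 23.3 and 17.6 and 0, and Crip3 at 0 in every library except those of KO GV (14.9 and 12.9). Ccnb1 (-0.07, adjusted p = 0.899), Mos (0.03, 0.962) and Cnot7 (0.23, 0.695) were not called at GV.

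At MI, 89.5% of genes stood higher in KO than in WT polysomes as deposited, with a median difference of 1.03. limma called 3257 genes higher and 54 lower in KO as deposited. With median scaling the split was 225 higher and 296 lower, and 63 genes called higher were then called lower. Without KO MI replicate 2 or 1 the higher calls numbered 1039 or 1271, and the lower calls 20 or 18; without WT MI replicate 2 the lower calls numbered 31. Ribosomal protein genes were higher in 62 of 80 cases, with 0 lower and 18 not called (70 higher adjusted over the list alone), for example Rpl23 (3.01, SE 0.334, adjusted p = 2.6e-04, 1.99 relative to the median) and Rpl14 (2.39, SE 0.144, adjusted p = 6.6e-06, 1.36 relative). With median scaling 11 higher and 5 lower were called. Camera gave this list adjusted p = 1.9e-06, and 0.0067 with an estimated correlation. Proteasome genes were higher in 28 of 35, with 0 lower and 7 not called (31 higher adjusted over the list alone), for example Psmb4 (2.36, 1.33 relative) and Psmb5 (2.13, 1.11 relative). With median scaling 2 higher and 1 lower were called. The camera test gave adjusted p = 2.0e-04, and 0.0236 with an estimated correlation. Neither list passed the camera threshold with median scaling (adjusted p = 0.261 and 0.435). With TPM the proteasome list did not pass (0.0509). Oxidative phosphorylation genes were higher in 55 of 85 and lower in 2, with 28 not called (65 and 2 adjusted over the list alone), for example Sdhb (2.18, 1.15 relative). With median scaling 3 and 9 were called in these directions. By camera it had adjusted p = 0.0146, but adjusted p = 0.143 with an estimated correlation, and 0.0820 without KO MI replicate 2. This call was also lost with TPM (0.604), median scaling (0.544), quantile normalization (0.163) and in a fit of the compared groups alone (0.0794).

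Where transcripts of the WT maturation program stood at MI against other genes depended on the setting. None of the first 3 lists here passed camera as deposited. Of the 20 maturation transcripts with a polyadenylation element 11 were higher, 0 lower and 9 not called (11 higher adjusted over the list alone; camera adjusted p = 0.845), but with median scaling 0 were higher and 7 lower, and the list lay below other genes (adjusted p = 7.6e-05). The oocyte-specific factors gave 15 higher, 1 lower and 14 not called of 30 (18 and 1 adjusted over the list alone; camera adjusted p = 0.592), while median scaling gave 0 higher and 15 lower (adjusted p = 9.3e-07, below other genes). Meiotic cell cycle genes gave 14 higher, 1 lower and 22 not called of 37 (14 and 1 adjusted over the list alone; camera adjusted p = 0.845), and 1 higher and 6 lower with median scaling (adjusted p = 0.0101, below other genes). With TPM the first 2 lists lay below other genes (adjusted p = 0.0103 and 2.0e-04). With the abundance trend removed they lay above other genes instead (adjusted p = 0.0187 and 0.00227), and with quantile normalization none of the 3 passed. As deposited, the list medians lay at -0.40, -0.56 and -0.26 relative to all genes. Ccnb1 was 0.63 higher in KO as deposited (adjusted p = 0.00105) and -0.37 with median scaling (adjusted p over the alternatives 5.8e-06 to 0.913). Mos and Gdf9 were not called as deposited (0.09, adjusted p = 0.362; 0.10, adjusted p = 0.194) and lower with median scaling (-0.90 and -0.89; adjusted p over the alternatives 1.5e-04 to 0.607 and 1.6e-06 to 0.622). Padi6 and Zp3 were 0.96 and 0.90 higher as deposited (adjusted p = 1.6e-06 for each) but -0.04 and -0.09 with median scaling, not called. Zona and subcortical complex genes were higher in 9 of 10, with 0 lower and 1 not called (10 higher adjusted over the list alone; 0 higher and 2 lower with median scaling). Their camera adjusted p was 0.035, but adjusted p = 0.273 with an estimated correlation. The call was lost when any 1 library outside KO GV was left out. The zona and subcortical call was also lost with TPM (0.874), median scaling (0.233), the replicate block (0.0707) and a fit of the compared groups alone (0.187). Their median lay at -0.11 relative to all genes, opposite in sign to the test, so camera as deposited can carry the shift.

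Single genes at MI moved far beyond the shift in both directions. Among the largest increases were the sulfate donor transporter gene Slc35b2 (0.39 and 0 FPKM in WT MI, 69.1 and 47.1 in KO MI; 5.62, adjusted p = 3.9e-05), Lypd3 (2.94 ± 1.24 against 159 ± 9.32 FPKM, mean ± SD; 5.38, adjusted p = 6.9e-06) and Stk36 (3.26 and 0 against 56.7 and 90.3; 5.14, adjusted p = 3.5e-04). The last 2 genes were also among those that fell from GV to MI in WT (-5.33 and -5.30), a comparison that shares the WT MI libraries. The meiotic kinase gene Aurkc was 2.38 higher (1.35 relative, adjusted p = 3.5e-05). Lower in KO were the branched-chain aminotransferase gene Bcat2 (166 ± 15.7 against 12.6 ± 1.23; -3.62, adjusted p = 5.3e-04), the meiotic chromosome gene Hormad1 (38.8 ± 1.31 against 1.68 ± 0.148; -3.90, adjusted p = 0.00123), the carboxypeptidase gene Agbl2 (26.2 ± 7.08 against 0.410 ± 0.283; -4.26, adjusted p = 8.9e-04) and the Dcpp1 and Dcpp2 pair (-6.39 and -5.67, adjusted p = 3.5e-05 and 1.3e-04). The cumulus and granulosa marker list lay below other genes (2 higher, 2 lower, 11 not called of 15, the same adjusted over the list alone; 0 higher and 3 lower with median scaling; camera adjusted p = 2.0e-04, and 0.0255 with an estimated correlation), although its median as deposited was 0.41. Its member Ptx3 was 32.1 and 40.2 in WT MI and 11.2 and 3.71 in KO MI (-2.29, adjusted p = 0.0191), a call lost without WT MI replicate 2 (0.0708) or KO MI replicate 2 (0.153), with a pseudocount of 0.1 and in a fit of the compared groups alone.

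At MII, genes differed between KO and WT polysomes far beyond a shift of all genes. limma called 2967 genes higher and 373 lower (1680 and 1216 with median scaling; 18 genes went from higher to lower), with a median difference of 0.81. The higher calls numbered 1884 without KO MII replicate 1 and 1891 without KO MII replicate 2, and the lower calls 216 without KO MII replicate 2 and 241 without KO MII replicate 1. The subcortical maternal complex genes were higher: Padi6 (2366 ± 100.4 FPKM in WT, 13248 ± 764 in KO; 2.48, SE 0.0448, adjusted p = 2.7e-10, 1.67 relative to the median), Ooep (225 ± 20.3 against 2232 ± 92.3; 3.31, SE 0.0885, adjusted p = 3.8e-09, 2.49 relative) and Tle6 (2.19, adjusted p = 1.7e-09, 1.38 relative). With Zp3 (1.67, 0.85 relative) they belong to a list with 8 of 10 higher, 1 lower and 1 not called (8 and 1 adjusted over the list alone). With median scaling 7 and 2 were called in these directions. In the camera test the list had adjusted p = 0.0119, but adjusted p = 0.174 with an estimated correlation. It did not pass with median scaling (0.0856) or in a fit of the compared groups alone (0.0652). Of 30 oocyte-specific factors 18 were higher, 1 lower and 11 not called (20 and 2 adjusted over the list alone; 9 and 6 with median scaling), for example Npm2 (2.57, 1.75 relative), Nlrp14 (2.26, 1.45 relative) and Bmp15 (1.5, 0.69 relative). Their camera adjusted p was 0.0325, but adjusted p = 0.28 with an estimated correlation. It was 0.0691 without either WT MI library, 0.0678 without WT MII replicate 2, 0.0535 without either KO GV library, 0.0524 without either KO MI library and 0.116 without KO MII replicate 2. It was 0.0595 with a pseudocount of 0.1, 0.344 with TPM, 0.810 with median scaling, 0.160 with quantile normalization, 0.0521 with the replicate block and 0.0847 in a fit of the compared groups alone.

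Ribosomal protein and proteasome genes stood higher in KO than in WT at MII beyond the shift of all genes, and oxidative phosphorylation genes did so in most settings. Ribosomal protein genes were higher in 57 of 80 cases and lower in 7, with 16 not called (59 and 7 adjusted over the list alone), for example Rpl5 (3.49, 2.67 relative) and Rps27a (3.32, 2.51 relative). With median scaling 34 and 11 were called in these directions. Against other genes camera gave adjusted p = 7.4e-05, and 0.0145 with an estimated correlation. Proteasome genes were higher in 27 of 35 and lower in 3, with 5 not called (28 and 3 adjusted over the list alone), for example Psmc1 (4.34, 3.53 relative) and Psmb7 (3.51, 2.70 relative). With median scaling 18 and 4 were called in these directions. The list had a camera adjusted p = 2.4e-04, and 0.0262 with an estimated correlation. Oxidative phosphorylation genes were higher in 54 of 85 and lower in 1, with 30 not called (57 and 1 adjusted over the list alone), for example Uqcrc1 (0 and 13.2 FPKM in WT, 65.7 and 138 in KO; 4.67, adjusted p = 0.00461, not called in a fit of the compared groups alone, 0.166). With median scaling 36 and 17 were called in these directions. Camera gave this list adjusted p = 2.4e-04, and 0.0484 with an estimated correlation. With median scaling these lists, in this order, had adjusted p = 0.0339, 0.0339 and 0.0856, so the last call was lost. Single cell cycle genes stood higher in KO: Cdk1 (3.41 and 2.59 relative, adjusted p = 1.6e-05), Tacc3 (4.08 and 3.27 relative, adjusted p = 4.1e-09) and Mcm5 (4.67 and 3.85 relative, adjusted p = 2.2e-06). The list of meiotic cell cycle control as a whole did not pass (13 higher, 1 lower and 23 not called of 37, 14 and 1 within the list alone; 8 and 12 with median scaling; camera adjusted p = 0.963). Also higher were the translation regulator Paip2 (2.52 and 1.70 relative, adjusted p = 4.9e-06) and the chaperones Dnaja1 (3.01 and 2.2 relative, adjusted p = 6.3e-07) and Hspa8 (2.17 and 1.35 relative, adjusted p = 8.7e-08). Dcp1a (-1.41 and -2.23 relative, adjusted p = 2.4e-04) and Exosc2 (-1.45 and -2.26 relative, adjusted p = 0.00142) were lower. In their list of 22 decapping, exosome and uridylation genes, 4 were called higher and 3 lower. Genes also named for a decrease from MI to MII in WT share the WT MII libraries, so opposite signs are in part expected.

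**Figure D3:**
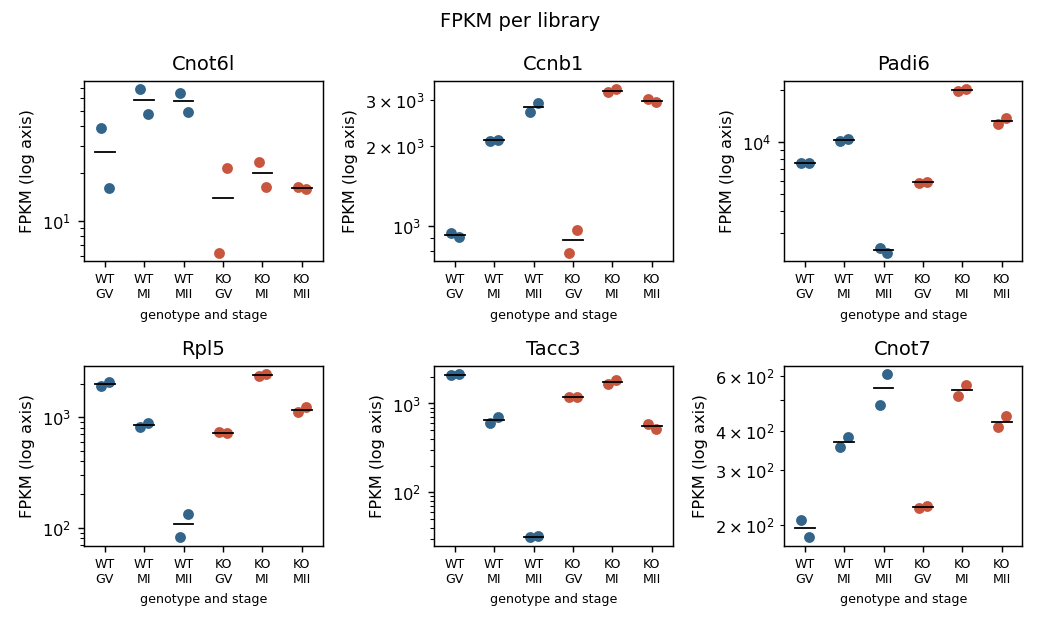
FPKM of Cnot6l, Ccnb1, Padi6, Rpl5, Tacc3 and Cnot7 in each library (points; log axis) by genotype and stage; bars mark the mean of 2 libraries. At MII Padi6 was 2.48 and Tacc3 4.08 higher in KO than in WT on the log2 scale, while Ccnb1 (0.09) was not called as deposited and was called lower with median scaling (-0.68).

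As a set, transcripts called higher from GV to MI in WT lay below the shift at MII, with a median KO minus WT difference of 0.04 against 0.85 in other genes, but single genes differed. Ccnb1 (0.09, adjusted p = 0.521), Mos (-0.05, 0.675) and Cnot7 (-0.34, 0.105) were not called as deposited. All 3 were called lower with median scaling (-0.68, -0.82 and -1.11), TPM and quantile normalization, while Ccnb1 was called higher with the abundance trend removed (adjusted p over the alternatives 4.5e-04 to 0.874 for Ccnb1 and 7.2e-05 to 1 for Mos). Cnot7 was called lower without WT MII replicate 1 (-0.50, adjusted p = 0.0294; adjusted p over the alternatives 3.0e-04 to 0.747). Gdf9 and Btg4 were 0.37 and 0.77 higher as deposited (adjusted p = 8.8e-04 and 1.2e-06) and stood at -0.40 and 0.01 with median scaling, so Btg4 lay near the shift (adjusted p over the alternatives 5.3e-06 to 0.233 and 3.5e-07 to 0.960). Of the 20 maturation transcripts 5 were higher, 2 lower and 13 not called (6 and 2 adjusted over the list alone; camera adjusted p = 0.114), against 0 higher and 13 lower with median scaling (adjusted p = 3.8e-04, below other genes). The ribosomal gene Rps27 was listed at 0.65 and 26.1 FPKM in WT MII and 673 and 742 in KO MII (6.73, adjusted p = 5.6e-04, not called in a fit of the compared groups alone, 0.0921), and Atpbd4 at 3.65 and 0.39 and 168 and 188 (6.14, adjusted p = 1.0e-05). Mrpl55 was listed at 0 in both WT MII libraries and 55.7 and 73.6 in KO MII, and Inha at 0 and 4.46 and 12.7. The reverse held for the stress-linked gene Nupr1 (47.0 and 65.2 in WT, 0 in both KO MII libraries), Agbl2 (18.1 and 18.9, 0 in both) and Dcpp1 (24.5 and 28.9, 0 in both). Bcat2 fell by 4.8 (adjusted p = 3.4e-05), and Ptx3 was at 17.1 and 15.3 in WT MII and 0.35 and 0 in KO MII.

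In the fit of all 12 libraries fewer genes were called between stages in KO than in WT. From GV to MI in KO limma called 1037 genes higher and 157 lower (549 and 229 with median scaling), and from MI to MII 19 higher and 838 lower (107 and 68 with median scaling, and 4 genes went from lower to higher). In fits of the compared groups alone this held from GV to MI (987 higher and 254 lower in KO, 249 and 1880 in WT) but reversed from MI to MII (26 higher and 1404 lower in KO, 0 and 0 in WT). The median absolute log2 difference between replicates was 0.513 in WT MI and 0.526 in WT MII. It was 0.309 in KO MI and 0.414 in KO MII, so counts of calls also depend on the spread of the groups. For MI vs GV the higher calls numbered 506 without KO MI replicate 2 and 558 without KO MI replicate 1, and the lower calls 52 without KO MI replicate 1, 53 without KO MI replicate 2, 79 and 87 without KO GV replicates 1 and 2, and 251 and 255 without WT MII replicates 1 and 2. For MII vs MI the lower calls numbered 198 without KO MI replicate 2, 233 without KO MI replicate 1, 352 and 377 without KO MII replicates 2 and 1, and 1563 and 1556 without WT MII replicates 1 and 2. The 19 higher calls were 8 and 11 without KO MI replicates 1 and 2, and 10 and 8 without KO MII replicates 1 and 2. Polyadenylation-element transcripts and oocyte-specific factors rose from GV to MI in KO too. Of the polyadenylation-element transcripts 14 of 20 rose, 0 fell and 6 were not called (15 higher adjusted over the list alone; 12 higher and 0 lower with median scaling), with camera adjusted p = 3.5e-08, and 0.0143 with an estimated correlation. Oocyte-specific factors rose in 20 of 30 cases, with 0 lower and 10 not called (20 higher and 2 lower adjusted over the list alone; the same with median scaling), with camera adjusted p = 4.5e-11, and 0.0143 with an estimated correlation. Zona and subcortical complex genes rose in 9 of 10, with 0 lower and 1 not called (10 higher adjusted over the list alone; 8 higher with median scaling, and not past the camera threshold after quantile normalization or with the abundance trend removed). Spindle genes rose in 26 of 46, with 0 lower and 20 not called (30 higher adjusted over the list alone; 11 higher with median scaling). Their camera adjusted p was 1.9e-07 and 3.5e-08, and 0.0161 and 0.00683 with an estimated correlation. Ribosomal protein genes gave 8 higher, 9 lower and 63 not called of 80 from GV to MI in KO (10 and 17 adjusted over the list alone). With median scaling 3 and 23 were called in these directions. The camera test gave adjusted p = 7.4e-04, below other genes, and 0.0143 with an estimated correlation. From MI to MII in KO ribosomal protein genes fell in 44 of 80 cases, with 0 higher and 36 not called (66 lower adjusted over the list alone; 8 with median scaling). The camera adjusted p was 1.6e-15, and 5.3e-04 with an estimated correlation. Oxidative phosphorylation genes fell in 35 of 85, with 1 higher and 49 not called (54 and 1 adjusted over the list alone; 4 and 2 with median scaling). Proteasome genes fell in 16 of 35, with 0 higher and 19 not called (24 lower adjusted over the list alone; 0 lower and 1 higher with median scaling). Camera adjusted p was 1.5e-08 and 1.9e-06, and 0.00752 for both with an estimated correlation.

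**Figure D4:**
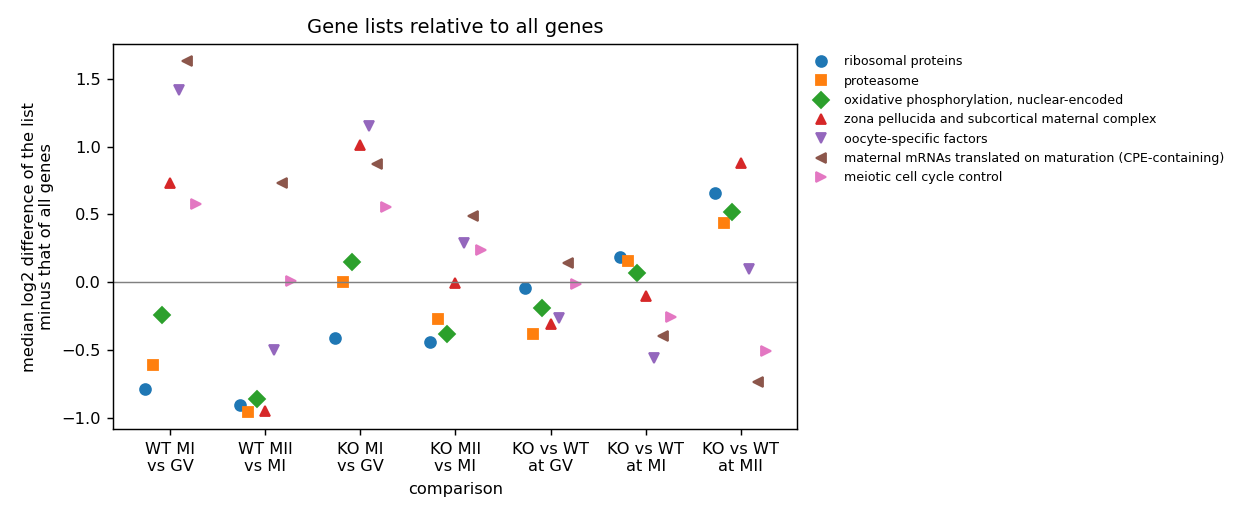
Median log2 change of 7 gene lists minus that of all genes tested (vertical axis, log2 units, 1 marker per list) in the 4 comparisons between stages and the 3 KO vs WT comparisons. In WT MII vs MI the ribosomal protein list lies below all genes, and in KO vs WT at MII it lies 0.66 above them.

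The 2535 genes called lower from GV to MI in WT had a median change of -1.93 there and -0.08 in KO (-1.19 and -0.38 with median scaling). In KO 94 of them were called lower, 138 higher and 2303 not called. The WT and KO changes differed for 1125 of them by the limma interaction test as deposited, all in the direction of a smaller decrease in KO. With median scaling it differed for 63 in that direction and 3 in the other. This test shares the WT libraries with the choice of the genes. At MII, where the group means rest on other libraries but the spread per gene is pooled over all 12, the same genes had a median KO minus WT difference of 1.37 against 0.66 in the other genes. Of them 1359 were called higher and 60 lower (camera p = 5.5e-14, and 1.6e-05 with an estimated correlation). Genes with a small spread are called more often in both comparisons. In separate fits, which share no library beyond the abundance filter, 1880 genes were called lower from GV to MI in WT. Their median at MII was 1.46 against 0.69 in other genes, and 427 were called higher and 18 lower (camera p = 1.0e-07, and 0.00218 with an estimated correlation). The 357 genes called higher from GV to MI in WT had a median change of 1.05 in WT and 1.32 in KO (1.84 and 1.01 with median scaling); in KO 283 were called higher, 1 lower and 73 not called. By the interaction test 77 of them changed more positively in KO and 10 more negatively as deposited, but 1 and 71 with median scaling, so the direction of this difference depended on the scaling. At MII, where their KO minus WT median was 0.04, 93 were called higher and 64 lower (camera p = 1.4e-07, below other genes, and 0.0171 with an estimated correlation). The share called higher was 26.1%, against 25.4% of other genes. In separate fits the 249 genes called higher in WT had a median of 0.08 at MII against 0.84 in other genes, with 44 called higher and 31 lower (camera p = 1.1e-05, and 0.0148 with an estimated correlation). The 1911 genes called lower from MI to MII in WT already stood lower in KO at GV, with a median of -0.23 against -0.02 in other genes; 100 were called lower and 2 higher (camera p = 4.4e-05, and 0.00161 with an estimated correlation). This choice too rests on the pooled spread, and it could not be repeated in separate fits, which called 0 genes between WT MI and WT MII.

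The genes called in KO vs WT overlapped between stages more than chance gives for decreases at each pair of stages: 12 shared between GV and MI (0.754 by chance; Fisher's exact test, 2-sided, adjusted p = 1.5e-11), 18 between GV and MII (5.21 by chance; adjusted p = 6.8e-06) and 22 between MI and MII (1.73 by chance; adjusted p = 6.3e-19). With median scaling these were 47 (2.54 by chance), 35 (10.4) and 197 (30.9). Leaving out each library in turn, the observed count over that expected ran from 12.9 to 41.3, 3.04 to 5.91 and 11.9 to 24.8 for these pairs, against 15.9, 3.45 and 12.7 with all libraries. Increases overlapped between MI and MII, with 1635 shared (828 by chance; adjusted p = 4.4e-298; 140 against 32.4 with median scaling), but the few increases at GV did not recur beyond chance as deposited (6 against 5.30 at MI and 4 against 4.83 at MII; Fisher's exact adjusted p = 0.798 for each). With median scaling these were 2 (0.405 by chance, adjusted p = 0.0734) and 4 (3.02 by chance, adjusted p = 0.531). Other settings turned this result: by Fisher's exact test, unadjusted, the observed count over that expected was 7.42 (p = 3.9e-05) and 2.82 (p = 2.4e-05) with quantile normalization, 2.29 (p = 3.7e-06) and 2.02 (p = 0.00194) with the abundance trend removed, and 1.77 (p = 0.0208) with TPM at MII. Without 1 library they ran from 0 to 1.38 at MI and 0.586 to 2.89 at MII. The comparisons at different stages share no library in their group means, and 6 overlaps were tested. They do share 1 spread per gene, pooled over all 12 libraries, so a gene with a small spread is called at several stages more often than the chance value allows. In separate fits of the compared groups the overlaps of MI and MII stayed, with 654 shared increases (344 by chance; Fisher's exact test, unadjusted, p = 3.9e-84) and 10 shared decreases (0.840 by chance; p = 8.9e-09). The overlaps with GV could not be checked that way, since its own fit called 0 genes.

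Several lists did not pass the camera threshold in any KO vs WT comparison as deposited, and their splits at MII changed with median scaling. At MII, CCR4-NOT and deadenylase genes other than Cnot6l gave 19 tested with 6 higher, 0 lower, 13 not called (6 and 0 within the list alone; 2 and 4 with median scaling; camera adjusted p = 0.963). Decapping, exosome and uridylation genes gave 22 tested with 4 higher, 3 lower, 15 not called (6 and 3 within the list alone; 1 and 8 with median scaling; camera adjusted p = 0.0812), and maternal RNA-binding regulators 26 tested with 9 higher, 2 lower, 15 not called (9 and 2 within the list alone; 5 and 5 with median scaling; camera adjusted p = 0.905). DNA methylation and chromatin modifiers gave 30 tested with 7 higher, 3 lower, 20 not called (9 and 3 within the list alone; 5 and 11 with median scaling; camera adjusted p = 0.12), transcription machinery 34 tested with 13 higher, 4 lower, 17 not called (13 and 5 within the list alone; 6 and 7 with median scaling; camera adjusted p = 0.298), and heat shock, unfolded protein and p53 response genes 21 tested with 8 higher, 1 lower, 12 not called (8 and 1 within the list alone; 4 and 1 with median scaling; camera adjusted p = 0.742). With median scaling the chromatin and transcription lists lay below other genes at MII (adjusted p = 0.0401 and 0.0339). The mitochondrially encoded list had 0 genes in the table; 2 early embryonic genes and 4 theca, stroma, endothelium and blood markers reached the abundance minimum, too few for a list test. Markers of other cells were a small part of each library: the cumulus and granulosa list held 0.0648% to 0.123% of the summed FPKM, the theca, stroma, endothelium and blood list 0.00206% to 0.00835%, and the early embryonic list 0.00171% to 0.0431%. A single gene carried much of each sum, named here after seeing the values: Serpine2 made up 60.8% to 93.8% of the first sum, Pecam1 43.7% to 98.4% of the second and Arg2 97.0% to 100% of the third. Without Serpine2 the first list held 0.00722% to 0.0285%, highest in the WT GV libraries (0.0268% and 0.0285%).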

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

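The tests on the shift of most genes at MI and the test on abundance of short transcripts were chosen only after the results were seen; those on removing the length and abundance trends were written down before their results were computed. The stage changes differed between genotypes by a test of the difference itself (limma interaction). From GV to MI, 1680 genes changed more positively in KO and 31 more negatively; with median scaling these were 69 and 111, and 14 genes went from the first to the second direction. From MI to MII the counts were 328 and 433 (480 and 285 with median scaling). Single libraries moved these counts. For MI vs GV they were 849 and 12 without WT GV replicate 1, 772 and 14 without WT GV replicate 2, 1075 and 17 without KO GV replicate 1, 720 and 7 without KO MI replicate 1, and 632 and 10 without KO MI replicate 2. The first count was 2611 and 2601 without WT MII replicates 1 and 2. For MII vs MI they were 147 and 177 without KO MI replicate 1, 161 and 169 without KO MI replicate 2, 184 and 227 without KO MII replicate 1, and 177 and 219 without KO MII replicate 2. The first count was 650 and 619 without WT MII replicates 1 and 2.

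Single genes differed in the same test. From GV to MI the KO minus WT difference in change was 0.70 (SE 0.126, adjusted p = 0.00589; -0.40 with median scaling) for Ccnb1, so its sign depended on the scaling, and 1.57 (SE 0.0513, adjusted p = 1.2e-07; 0.47 with median scaling) for Zp3. From MI to MII it was -0.54 (SE 0.126, adjusted p = 0.0296; -0.31 with median scaling) for Ccnb1, 1.53 (SE 0.0634, adjusted p = 5.4e-07; 1.76 with median scaling) for Padi6 and 0.76 (SE 0.0513, adjusted p = 1.7e-05; 0.99 with median scaling) for Zp3.

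Most genes stood higher in KO than in WT at MI, with a median log2 difference of 1.03. Lower depth in WT MI that empties low genes is argued against by genes with a mean FPKM of at least 100, whose median difference was still 0.89. A few abundant genes taking more of the WT MI signal are argued against as the whole cause. The share left outside the 100 most abundant genes differed by 0.21 on the log2 scale. With every library rescaled to the same total (TPM) the median difference was 0.45, so such genes stay open as part of the cause. A single scale factor per library cannot produce the differences between genes, since 16.7% of genes with a mean FPKM of at least 100 were called after median scaling. For the shift of 1.03, such a factor, a genuine excess of polysome-bound RNA and reads outside the listed genes cannot be told apart. No external standard or read count is given. Libraries were made from 500 pg of pre-amplified cDNA, and FPKM are scaled by library size. An excess of total RNA alone would then not show. The genotype remains an open, untested explanation for the shift.

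Short transcripts stood lower in WT MII than in WT MI: with genes in 5 equal classes of transcript length, the median change went from -0.51 in the shortest class to 0.05 in the longest. For ribosomal protein and proteasome genes, a length trend of the libraries as the whole cause is argued against by their values after its removal. They still lay at -0.69 (camera adjusted p = 3.0e-06) and -0.72 (3.2e-04) relative to all genes. For short transcripts in general this removal cannot decide, since it takes out the pattern itself. Low abundance of short transcripts is argued against by genes with a mean FPKM of at least 200, where the shortest class lay at -0.53 relative to the longest (SE 0.119). A length trend as part of the cause stays open, and the stage itself is an untested biological explanation; KO MII vs MI had a trend in the same direction (-0.71 to -0.35).

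Abundant transcripts stood lower in KO than in WT at GV. Of the 50 genes most abundant in WT GV 44 were lower, 30 were called lower and 2 called higher (41, 25 and 2 with median scaling). That ranking uses the WT GV libraries compared, which by itself favours lower values in KO. Genes were also put in 5 equal classes of mean FPKM over the 12 libraries. The median difference was -0.17 in the most abundant class and 0.04 in the least abundant. A length trend of the libraries is argued against as the cause, since 160 of the 163 lower calls stayed after its removal. With the abundance trend removed 73 of the 163 stayed, and the median difference of the 163 genes went from -0.92 (median SE 0.13) to -0.67 (median SE 0.13), so many calls ended because the fold shrank. A compression of abundant transcripts in the KO GV libraries may therefore underlie part of the decrease and cannot be told apart from a genotype effect on abundant transcripts, since both KO GV libraries carry the trend. The genotype stays open as an untested explanation.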

How the results depend on the processing

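The 2 alternatives that remove a trend with length or with abundance were chosen after seeing the data; the others were planned. Of 135 called results of named genes, those that kept direction and call numbered 134 without the filter, 134 with the replicate block, 133 with a pseudocount of 0.1, 132 with TPM, 128 with median scaling, 131 with quantile normalization, 135 and 132 with the length and the abundance trend removed, 81 in fits of the compared groups only, and 132 without any 1 library. Of 39 list calls 39, 37, 36, 26, 26, 29, 39, 29, 35 and 32 did so in the same order, and 25 with an estimated correlation. The 3 sets of WT stage genes kept direction and call under every alternative run. In fits of the compared groups only, the set lower from MI to MII was empty. Why values below differ was not tested, but such fits have fewer libraries and residual degrees of freedom.

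With a pseudocount of 0.1, values that moved were: calls KO vs WT at MI 35 lower. Positions were KO GV 0.0869, KO MI 0.0813, KO MII 0.313, WT MI 0.493. Cnot6l at MII -1.80 (adjusted p = 0.0534), no longer called. Without the filter: calls KO MII vs MI 31 higher, KO vs WT at GV 43 higher. Positions were KO GV 0.0910, KO MI 0.113, WT MI 0.526. Cnot6l at MII -1.75 (adjusted p = 0.0688), no longer called. With the replicate block: calls KO vs WT at GV 12 higher. Cnot6l at MII -1.75 (adjusted p = 0.0533), no longer called. The replicate number is not a pairing: deviations of replicate 1 from its group mean correlated between groups across genes at -0.0292 to 0.0547.

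With TPM: calls KO MI vs GV 316 higher and 440 lower, KO MII vs MI 60 higher and 118 lower, KO vs WT at GV 48 higher and 76 lower, KO vs WT at MI 490 higher and 157 lower, KO vs WT at MII 748 lower, WT MII vs MI 1060 higher, interaction MI vs GV 113 higher and 81 lower. Positions were KO GV 0.0278, KO MI 0.219, KO MII 0.389, WT MI 0.479. Observed over expected overlap was GV and MII higher 1.77 (Fisher's exact p = 0.0208). Reversed there were genes Ccnb1 in KO vs WT at MI -0.0226, Ccnb1 in KO vs WT at MII -0.37, Gdf9 in KO vs WT at MI -0.55, Gdf9 in KO vs WT at MII -0.0861, Mos in KO vs WT at MI -0.55; lists (camera adjusted p) polyadenylation-element transcripts in KO vs WT at MI 0.0103.

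With median scaling: calls KO MI vs GV 549 higher, KO MII vs MI 107 higher and 68 lower, KO vs WT at GV 100 lower, KO vs WT at MI 225 higher and 296 lower, KO vs WT at MII 1680 higher and 1216 lower, WT MI vs GV 919 higher and 745 lower, WT MII vs MI 1331 higher, interaction MI vs GV 69 higher and 111 lower, interaction MII vs MI 285 lower. Positions were KO GV 0.0605, KO MI 0.201, KO MII 0.346, WT MI 0.402. Cnot6l at MI -2.44 (adjusted p = 0.0412), now called. Reversed there were genes Ccnb1 in KO vs WT at MI -0.37, Ccnb1 in KO vs WT at MII -0.68, Gdf9 in KO vs WT at MI -0.89, Gdf9 in KO vs WT at MII -0.40, Mos in KO vs WT at MI -0.90, Mos in WT MII vs MI 0.33, Padi6 in KO vs WT at MI -0.0393, Zp3 in KO vs WT at MI -0.0910, Zp3 in WT MI vs GV 0.44; lists (camera adjusted p) polyadenylation-element transcripts in KO vs WT at MI 7.6e-05, meiotic cell cycle in KO vs WT at MI 0.0101, oxidative phosphorylation in KO vs WT at MI 0.544, zona and subcortical complex in KO vs WT at MI 0.233.

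With quantile normalization: calls KO MI vs GV 571 higher and 347 lower, KO MII vs MI 66 higher and 79 lower, KO vs WT at GV 50 higher and 88 lower, KO vs WT at MI 220 higher and 149 lower, KO vs WT at MII 1492 higher and 895 lower, WT MI vs GV 867 higher and 736 lower, WT MII vs MI 1071 higher, interaction MI vs GV 90 higher and 81 lower, interaction MII vs MI 143 lower. Positions were KO MI 0.219, WT MI 0.396. Observed over expected overlap was GV and MI higher 7.42 (Fisher's exact p = 3.9e-05), GV and MII higher 2.82 (Fisher's exact p = 2.4e-05). Reversed there were genes Ccnb1 in KO vs WT at MII -0.52, Gdf9 in KO vs WT at MI -0.51, Gdf9 in KO vs WT at MII -0.19, Mos in WT MII vs MI 0.30.

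With only the compared groups in the limma fit: calls KO MI vs GV 254 lower, KO MII vs MI 1404 lower, KO vs WT at GV 0 higher and 0 lower, KO vs WT at MII 1365 higher and 172 lower, WT MII vs MI 0 higher and 0 lower, interaction MII vs MI 186 higher. Cnot6l at MI -1.49 (adjusted p = 0.0475), now called. Beside the 0 calls, an unadjusted p under 0.05 gave 480 higher and 1052 lower in KO vs WT at GV and 857 higher and 1780 lower in WT MII vs MI.

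With the length trend removed: positions KO GV 0.0860, KO MI 0.0950, WT MI 0.518. With the abundance trend removed: calls KO MI vs GV 608 higher, KO MII vs MI 12 higher, KO vs WT at GV 33 higher and 73 lower, WT MI vs GV 196 higher. Positions were WT MI 0.515. Observed over expected overlap was GV and MI higher 2.29 (Fisher's exact p = 3.7e-06), GV and MII higher 2.02 (Fisher's exact p = 0.00194). Reversed there were genes Btg4 in WT MI vs GV -0.31, Gdf9 in WT MI vs GV -0.55; lists (camera adjusted p) oocyte-specific factors in KO vs WT at MI 0.00227.

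Leaving out each library in turn, where the lone library left in its group is assumed to vary like the other groups, gave these ranges of higher and lower calls: 3 to 27 and 68 to 210 for KO vs WT at GV, 1039 to 4283 and 18 to 69 for KO vs WT at MI, 1884 to 3101 and 216 to 380 for KO vs WT at MII, 216 to 412 and 1176 to 3316 for WT MI vs GV, 496 to 652 and 1517 to 2013 for WT MII vs MI, 506 to 1302 and 52 to 255 for KO MI vs GV, 8 to 26 and 198 to 1563 for KO MII vs MI, and 632 to 2611 and 7 to 43 and 147 to 650 and 169 to 575 for the interactions. Cnot6l ranged from -1.84 to -0.21 at GV, -1.75 to -1.24 at MI and -1.95 to -1.55 at MII. Positions were 0.0705 to 0.122 for KO GV, 0.0928 to 0.144 for KO MI, 0.340 to 0.405 for KO MII, 0.470 to 0.542 for WT MI. The set differences stayed at 0.62 to 0.82, -0.84 to -0.74 and -0.24 to -0.19. Observed over expected overlaps, lower and higher, were 12.9 to 41.3 and 0 to 1.38 for GV and MI, 3.04 to 5.91 and 0.586 to 2.89 for GV and MII, and 11.9 to 24.8 and 1.86 to 2.89 for MI and MII.

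The tables per library equal the series table to 2 decimals and so give no other value for Cnot6l. The overlap of higher calls at GV and MII was 0.828 of that expected as deposited, so the values above 1 given for other scalings reversed it. Stage positions have no fit of the compared groups or with a block. Read depth is not known, so it cannot be said how far depth limits the calls among low genes.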

Other observations

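All counts here were chosen only after the calls were seen. KO vs WT called 6 genes lower at all 3 stages (0.0241 by chance) and 3 higher (1.35 by chance). With median scaling these were 25 (0.264) and 2 (0.0583), with TPM 13 and 4, and with quantile normalization 6 and 6. The chance values take the calls as independent, but all 3 comparisons share 1 pooled spread per gene, which raises the counts expected by an unknown amount. The lower genes were Cks2, Dcpp1, Dcpp2, Fam54a, Ggct and H2-Aa, all but Cks2 also with median scaling, and the higher genes Btg4, Gm19757 and Lrrc51, of which Gm19757 alone was also called with median scaling. Ggct, which encodes an enzyme of glutathione metabolism, fell by 0.63, 1.19 and 1.75 at GV, MI and MII (limma adjusted p = 0.0119, 5.0e-05 and 1.0e-06). The class II antigen gene H2-Aa fell by 2.64, 2.5 and 2.93 (adjusted p = 0.00440, 0.00125 and 2.3e-04). Lrrc51 was listed at 0 in both WT GV libraries. The study's labels do not describe the genetic background beyond the strain, so differences present at every stage were not assigned to Cnot6l or to linked or strain variants.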
